A study of Caenorhabditis elegans with 2 samples.

How the data were processed

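The samples were 2 ChIP-seq libraries, biological replicates 1 and 2 per the labels, from whole L1 hermaphrodites of a strain with an integrated transgene for HLH-4 fused to GFP and FLAG. Chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. Both libraries form 1 group. A control library named in the labels as a possible control was not analysed here.

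The deposited files are headerless peak lists on 2 genome builds, ce11 and ce10. For each build they hold 1 list of regions per replicate, 1 list from the pooled replicates and the optimal IDR-thresholded peaks. Per the descriptive text deposited beside the lists, the authors made the region lists from alignments of each library, or of the pooled libraries, together with a control, and made the optimal peaks from both replicate lists and the pooled list. The region lists hold both peaks and background, as input for the IDR step. The aligner, the peak caller, their versions and the read counts are not given in the sources used here, so depth is unknown. In the deposited lists each region has a signal value, whose normalization is not given in the sources used here and which was used to describe and rank regions within 1 list. Pearson's r is the exception, as it uses the values of both replicate lists, for which no common normalization is known. It does not depend on the linear scale of either list, and Spearman's rho uses ranks within each list. The deposited −log10 q-value of each region ran from 1.36 to 2.32 over the optimal peaks and was not used to select regions. The deposited offset of the summit from the region's start gave the summit. Positions were written 1-based.

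The lists were checked before use. All 545 optimal peaks on ce11 have the same start, end and signal value as regions of the pooled list, and they are the 545 regions with the highest signal values there. Full-width regions span 330 bp in the pooled list, with the summit at the midpoint in each, and the 107 narrower regions of the pooled list are all optimal peaks. No region ends past its chromosome on the reference. Region widths differ between replicates (330 and 340 bp). Positions, genes and sequences refer to ce11, compared with the WBcel235 genome sequence and the Ensembl release 115 gene annotation; ce10 lists were used for counts and overlaps only.

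Lower-ranked regions, the background measured in the same libraries, were the regions of the pooled list from rank 15001 on that overlapped no optimal peak (14976 regions). A summit was assigned to the protein-coding gene with the nearest start among those for which it lay from 2000 bp upstream to 500 bp downstream of the start. Summit features were read from the annotation in the order coding exon, 5' UTR, 3' UTR, pseudogene, intron, non-coding RNA exon and intergenic. E-boxes were searched on both strands within 50 bp either side of the summit, a window of 101 bp. Shares were compared by two-sided Fisher's exact tests, and summits with their own flanks at 300 bp by a two-sided exact sign test over peaks. Gene lists were compared by two-sided Fisher's exact tests against the 9528 protein-coding genes assigned a region of any strength, with 0.5 added to each cell for the odds ratio. Related genes, and the peaks at them, were counted as independent. Benjamini-Hochberg adjustment was over the 10 E-box classes, the 6 chromosomes, the 7 features or the 23 lists, with a threshold of 0.05.

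Agreement between replicates was measured as the overlap, by at least 1 bp, of the 545 strongest regions, against 10000 random rankings of replicate 2. A 2-component copula mixture, the model behind the IDR, was also fitted to the signal ranks of one-to-one overlapping pairs. Regions within a library are not biological replicates, so these p-values compare lists. Single-replicate values use the 545 strongest regions of 1 replicate. Their lower-ranked background stayed that of the pooled list of both replicates, less the regions that overlapped those used.

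The gene lists, the rule for naming genes, the alternatives other than the 4 below and these tests were fixed before the data were examined: overlap of the strongest regions, IDR mixture, promoter share, E-box share, classes, flanks and rank, gene lists and chromosomes. The rule names the genes at the 20 strongest optimal peaks, up to 4 members per list with the highest signal values, and hlh-4. The tests of summit features, of distance to the gene start and of correlation, the search for 8-base sequences, the tests of explanations, of single chemoreceptor families and of E-boxes at peaks without a gene start in reach, and 4 alternatives were not among them and were added after the data had been seen. Alternatives covered the genome build, stricter peaks, each replicate left out, the overlap and number of regions, the promoter and E-box windows, the backgrounds, the gene assignment and the flank, rank and locus distances.

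The E-box class test, the 8-mer search, the gene list test, the IDR mixture and the overlap of the strongest regions were tested on simulated data first, and the other comparisons were not. With CAGGTGAA placed in 20% of 545 lower-ranked windows, the class test recovered it in 20 of 20 runs, with 0 other calls and 0 calls without it, and the 8-mer search ranked it first. With chemoreceptor genes drawn 2.5 times as often among 312 genes, the list test called the list in 99 of 100 runs, with 2 calls of other lists over all runs and 1 call over 100 runs without an effect. In 9000 simulated pairs of which 899 were reproducible, the mixture called 718 at an IDR of 0.05, and 5.71% of these were false. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.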

Results

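Genome binding of HLH-4, a basic helix-loop-helix (bHLH) factor of the Achaete-Scute family known from work on the ADL chemosensory neurons, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole first-stage (L1) Caenorhabditis elegans larvae. The hermaphrodite animals carried an integrated transgene that makes HLH-4 with a C-terminal GFP-FLAG tag, and were collected 6 hours after synchronization by starvation. Chromatin was precipitated with an antibody against GFP in 2 biological replicates, which form 1 group, so the design holds no comparison between groups and each test below compares sets of regions or genes. Each replicate list and the list from the pooled replicates held 30000 ranked regions. The authors' optimal set, those peaks that passed their irreproducible discovery rate (IDR) analysis, held 545 peaks on the ce11 genome build, which is used for every position below. Read depth is unknown, so no interval based on depth is given; intervals are 95% exact Clopper-Pearson intervals over regions or genes and cover counting error only.

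The tagged gene itself carried a peak. The peak lay at III 9738883 to 9739212 over the 5' end of hlh-4 (III 9737472 to 9739054, minus strand), with its summit at 9739048, in the 5' UTR 6 bp downstream of the gene start. An E-box of the CACCTG class lay within 50 bp of the summit. It ranked 370 of the 545 peaks with a signal value of 54.7, and the replicates differed on it: the overlapping region ranked 178 in replicate 2 and 9765 in replicate 1. Replicate 1 had a stronger region elsewhere over hlh-4, ranking 621, with its summit 686 bp downstream of the gene start and without a CASSTG E-box. A second optimal peak lay 12363 bp upstream of the gene start, at III 9751252 to 9751581, ranking 416, without such an E-box. Regions of any strength were dense around the gene, with 26 summits of the pooled list within 20000 bp of its start against a median of 12 for protein-coding genes.

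The strongest peak of the pooled replicates, at X 12022603 to 12022837 in intergenic sequence 3043 bp upstream of B0198.2, was also the strongest in each replicate. The peak at srz-11, a gene of a nematode chemoreceptor family, was second in all 3 lists, and the peak at the chemoreceptor gene sre-41 ranked 3 in the pooled list and in replicate 1 and 4 in replicate 2. Signal values, which are the authors', ran from 43.1 to 379.5 over the optimal peaks with a median of 65.4. Of the 545 peaks, 542 overlapped a region in replicate 1 and 542 in replicate 2, and 424 and 437 respectively were among the 545 strongest regions of that replicate. The optimal set was made from both replicate lists and the pooled list, so these counts depend on that selection. The same holds for the correlations within the optimal peaks below, and neither is independent evidence of agreement. Among the 545 strongest regions of replicate 1, 342 (62.8%, interval 58.5% to 66.8%) overlapped one of the 545 strongest of replicate 2, whereas random ranks gave a mean of 10.4 and a highest count of 25 (one-sided permutation test over regions, 10000 draws, p = 0.0001, the smallest these draws can give). The shared portion was 32.4% for the 2000 strongest regions and 22.96% for the 5000 strongest. Random ranks gave a mean of 4.63% and 8.77% there, against 1.90% for the 545 strongest. A separate IDR fit to the 9476 overlapping region pairs of the replicates gave 643 regions at an IDR of 0.05. Across these pairs, which are regions and not independent replicates, signal values had a Pearson's r of 0.80 and a Spearman's rho of 0.26, and across the 539 optimal peaks present in both replicates 0.77 and 0.50 (permutation p = 1e-05 for each of the 4, the smallest that 100000 permutations can give; Benjamini-Hochberg over the 4 leaves it at that value). Whether the signal values of both lists share a normalization is not given in the sources used here. A difference in linear scale would leave both coefficients unchanged. A non-linear difference would bear on Pearson's r and not on the rank-based rho.

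**Figure D1:**
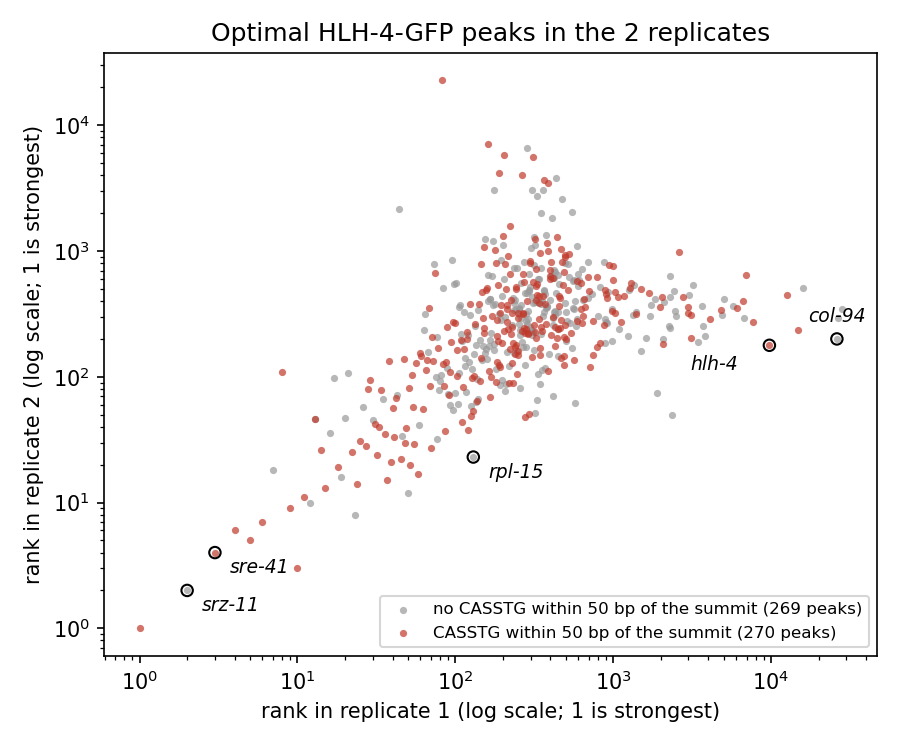
Rank by the authors' signal value, with 1 the strongest, of the overlapping region in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 539 optimal peaks with a region in both, red where a CASSTG E-box lies within 50 bp of the summit. The peaks at srz-11 and sre-41 sit at the strong end, lower left, in both replicates, and the peak at hlh-4 ranks 9765 in replicate 1 and 178 in replicate 2.

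The genes at the strongest sites were led by chemoreceptor genes. Of the 20 strongest peaks, 15 had a protein-coding gene start in reach (summit from 2000 bp upstream to 500 bp downstream of the start), and 5 of these genes were chemoreceptors: srz-11 (V 15162772 to 15163019, signal value 354.7), sre-41 (II 12387582 to 12387869, 274.1), srz-82 (IV 3482667 to 3482874, 250.2), sre-27 (II 12418096 to 12418285, 198.2) and srz-10 (V 15309074 to 15309288, 178.6). Their summits were all intergenic and 93 to 593 bp upstream of the gene start. The other 10 genes were Y22F5A.11, K10D6.4, F56G4.6, Y56A3A.7, C25E10.17, F48G7.4, cux-7, Y105C5A.15, gcsh-2, which encodes a glycine cleavage system H protein, and C18H7.6. The K10D6.4 summit lay in a coding exon near the start, and the gcsh-2 summit in an intron of another gene model 195 bp upstream of the gcsh-2 start. A CASSTG E-box lay at 14 of the 20 summits. The summits at srz-11, C25E10.17, F56G4.6, Y56A3A.7 and cux-7, and the 1 at V 10465613 to 10465803 with no gene start in reach, lacked it. Those at F56G4.6, Y56A3A.7 and cux-7 held a different sequence that recurs among E-box-free peaks.

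Peaks lay close to gene starts and in intergenic sequence more often than weak regions of the same libraries. Summits within the promoter window made up 323 of 545 (59.3%, interval 55.0% to 63.4%) against 41.6% of the 14976 lower-ranked regions (two-sided Fisher's exact test, p = 5.2e-16). The difference of 17.6 percentage points was 9.53 with a window of 5000 bp upstream to 1000 bp downstream and 23.3 with 1000 bp upstream to 200 bp downstream, and both passed (Fisher's exact test, p = 9.5e-07 and 7.0e-32). Using each replicate's 545 strongest regions alone, the value was 58.8% ± 2.21 (SD, n = 2). The median distance to the nearest gene start was 904 bp at peaks and 1530 bp at lower-ranked regions (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Intergenic sequence held 64.6% of peak summits and 35.6% of lower-ranked ones, and 5' UTRs held 4.77% against 1.37%. Coding exons held 5.32% against 22.9%, introns 21.8% against 33.5% and 3' UTRs 0.55% against 3.91% (Fisher's exact test, Benjamini-Hochberg over 7 features, the largest of these 5 adjusted p = 2.5e-06). Non-coding RNA exons held 2.39% against 0.72%, and pseudogenes 0.55% against 2.10% (Fisher's exact test, adjusted p = 0.00038 and 0.0079).

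Chromosome V held 164 of the 545 peaks (30.1%, interval 26.3% to 34.1%) against 20.7% of lower-ranked regions (Fisher's exact test, Benjamini-Hochberg over the 6 chromosomes, adjusted p = 2.6e-06). Chromosome II was also over-represented (15.96% against 12.01%, Fisher's exact test, adjusted p = 0.015). Chromosome I (9.91% against 14.1%, adjusted p = 0.015) and chromosome IV (16.5% against 20.5%, adjusted p = 0.034) held fewer peaks by the same exact test. Chromosomes III and X did not pass it (exact test, adjusted p = 0.12 for each). Without the peaks at chemoreceptor genes, an alternative chosen after seeing the data, the difference on V fell from 9.36 to 5.59 percentage points and still passed the exact test (adjusted p = 0.020), while I and IV did not pass (adjusted p = 0.082 for each). With these 55 fewer peaks the difference on IV was −3.59 points against −4.02, and on I it was −3.04 against −4.15. The background kept its regions at chemoreceptor genes, so the fall on V follows in part by construction. The chromosome II difference did not pass with replicate 2 alone (exact test, adjusted p = 0.078). With chromosome length as the background in an exact binomial test, neither II nor IV passed (adjusted p = 0.76 for each), and III passed narrowly as holding fewer peaks (adjusted p = 0.049999).

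E-boxes with GC or CC/GG centres (CAGCTG, CACCTG or CAGGTG, together CASSTG), the sites that Achaete-Scute factors bind with their E-protein partners, were the main sequence feature at the summits. They lay within 50 bp of the summit in 271 of 545 peaks (49.7%, interval 45.4% to 54.0%) and in 4.60% of lower-ranked regions (interval 4.27% to 4.95%), a 10.8-fold difference (two-sided Fisher's exact test, p = 1.5e-188). The 545 strongest regions of each replicate alone gave 43.2% ± 0.91 (SD, n = 2). For the optimal peaks the difference was 14.2-fold with 25 bp and 6.96-fold with 100 bp either side of the summit. Against 2725 lower-ranked regions of the same GC content it was 7.25-fold with 50 bp. Within peaks, the sites were centred on the summit: windows 300 bp to the left and right held them in 4.59% and 4.77% of peaks, and 253 peaks had a site at the summit and not on the left against 7 with the reverse (two-sided exact sign test, p = 1.6e-65; right side 252 against 7, p = 3.2e-65). The density of sites reached 160 per 1000 peaks in the 20-bp bin starting at the summit, where lower-ranked regions had 9.68 per 1000.

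**Figure D2:**
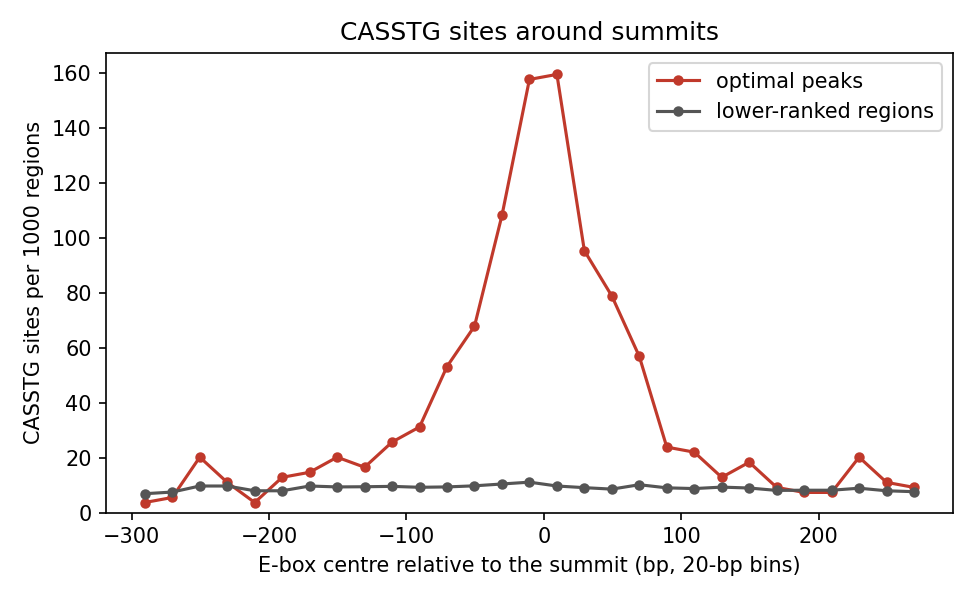
CASSTG sites per 1000 regions (y axis) by distance of the site's centre from the summit in 20-bp bins (x axis), for the 545 optimal peaks in red and the 14976 lower-ranked regions in grey. Peaks reach 160 sites per 1000 at the summit and fall to the level of the lower-ranked regions, which stay between 6.88 and 11.1, toward the ends of the window.

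Among the 10 E-box classes, 6 were more frequent at peaks than in lower-ranked regions and 1 was less frequent (Fisher's exact test, Benjamini-Hochberg over the 10). CACCTG, read with its reverse complement CAGGTG, stood highest, at 37.8% of peaks against 2.80% (13.5-fold, Fisher's exact test, adjusted p = 9.6e-152). CAGCTG was at 15.05% against 1.84% (8.16-fold, Fisher's exact test, adjusted p = 2.9e-43). By the same exact test the increases were smaller for CACATG (8.26% against 3.25%, adjusted p = 1.6e-07), CACGTG (3.85% against 1.34%, adjusted p = 8.8e-05), CAGATG (7.34% against 3.96%, adjusted p = 0.00071) and CAAATG (12.1% against 8.66%, adjusted p = 0.0099). CAACTG was less frequent (2.75% against 5.31%, Fisher's exact test, adjusted p = 0.0098), while CAAGTG, CAATTG and CATATG did not pass. With either replicate alone, CAAATG (adjusted p = 0.21 and 0.76) and CAACTG (adjusted p = 0.090 and 0.20) no longer passed the exact test, and with replicate 2 alone CAATTG passed as less frequent (adjusted p = 0.0497). CAAATG also did not pass with the upper 272 peaks or with windows of 25 or 100 bp either side (exact test, adjusted p = 0.15, 0.18 and 0.43), CAACTG did not pass with 25 bp, where its ratio was 0.43 against 0.52 with 50 bp on fewer peaks (6 against 15; adjusted p = 0.058), and CAATTG passed as less frequent with 100 bp (adjusted p = 0.014). Against 2725 lower-ranked regions of the same GC content, all 6 shares at peaks were still above the background. CACCTG (9.04-fold), CAGCTG (5.62-fold) and CACATG (2.14-fold) passed the exact test there. CACGTG (1.62-fold against 2.89-fold before matching, adjusted p = 0.071), CAGATG (1.44-fold against 1.85-fold, adjusted p = 0.056) and CAAATG (1.32-fold against 1.40-fold, adjusted p = 0.056) did not pass the exact test with this smaller background, while CAACTG and CAATTG passed as less frequent (adjusted p = 0.00057 and 0.043).

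The strongest 181 peaks held CASSTG in 55.2% and the weakest 181 in 45.9%, a difference of 9.39 percentage points that did not pass the test (two-sided Fisher's exact test, p = 0.092). Between the strongest and weakest 136 peaks the difference was 16.2 percentage points (Fisher's exact test, p = 0.011), and between the strongest and weakest 272 it was 6.99 points (p = 0.12). With windows of 25 and 100 bp either side of the summit the first comparison did not pass the exact test either (9.39 and 7.73 points, p = 0.073 and 0.16). The 36 peaks with the other recurring sequence, picked in E-box-free peaks and described below, lay mostly among the strongest 181. Of these 36, 35 lacked CASSTG. They were kept in these comparisons, and the trend without them was not tested.

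**Figure D3:**
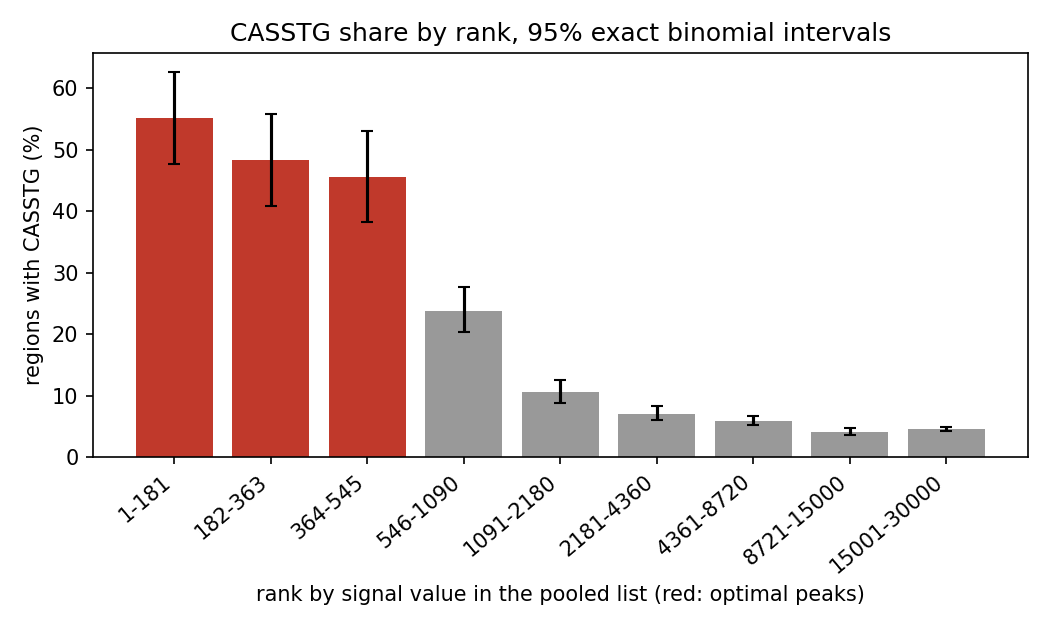
Percent of regions with a CASSTG E-box within 50 bp of the summit (y axis) by rank of signal value in the pooled list (x axis), with 95% exact binomial intervals; red bars are the optimal peaks. The share is 55.2%, 48.4% and 45.6% in the red bars, 23.9% just below them and 4.62% in the last bar.

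Chemoreceptor families were the 1 of 23 gene lists that was over-represented at peaks. The peaks were assigned to 312 genes, out of 9528 protein-coding genes with a region of any strength. Chemoreceptor genes made up 52 of the 312 (16.7%) against 7.38% of the other background genes (log2 odds ratio 1.34, two-sided Fisher's exact test, Benjamini-Hochberg over the 23 lists, adjusted p = 2.3e-06). Of the 52, 33 were on chromosome V. The leading members by signal value were srz-11, sre-41, srz-82 and sre-27.

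**Figure D4:**
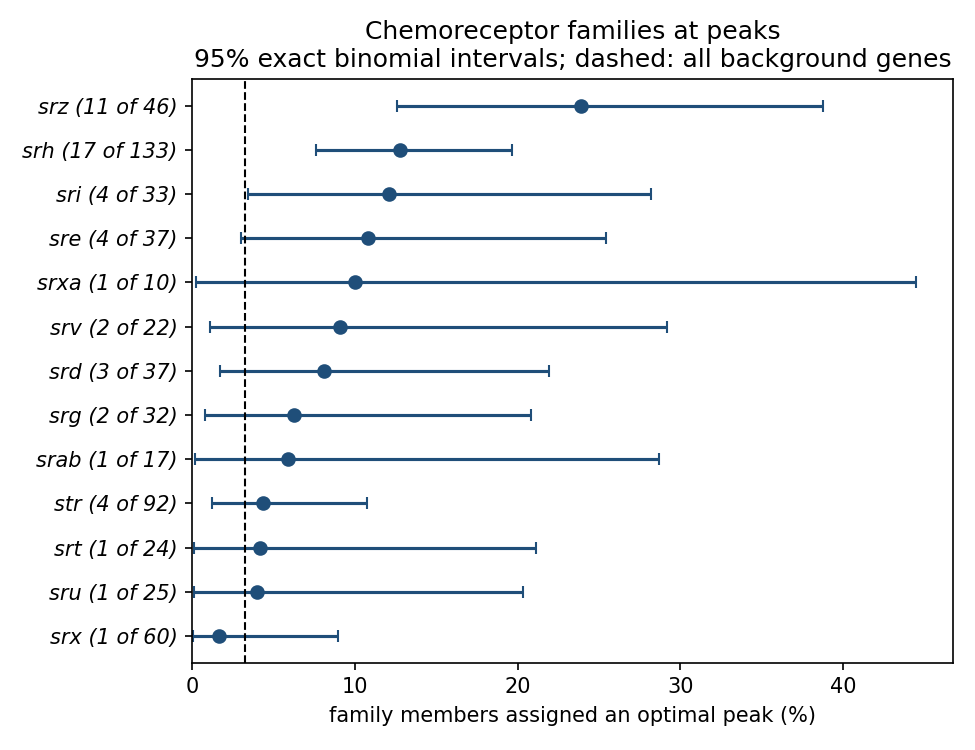
Percent of the background members of each chemoreceptor family assigned an optimal peak (x axis), with 95% exact binomial intervals, for the 13 families with at least 1 such gene; the dashed line is the 3.27% of all 9528 background genes. The srz family, with 11 of 46 members, the srh family, with 17 of 133, and the sri family, with 4 of 33, lie above the line with their whole intervals, and srx, with 1 of 60, lies below it with an interval that crosses it.

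Ribosomal protein genes were at peaks in 5 of 34 cases (log2 odds ratio 2.48, Fisher's exact test, adjusted p = 0.053), which did not pass. Their strongest 4 were rpl-15 (signal value 127.4, 332 bp upstream), rpl-35 (91.2), rps-1 (79.8) and rpl-3 (78.8), and none of these summits held CASSTG. The region at rps-1 ranked 1905 in replicate 1 and 75 in replicate 2. The list passed the exact test in the upper 272 peaks (log2 odds ratio 3.46, adjusted p = 0.0030) and with a promoter window of 1000 bp upstream to 200 bp downstream (3.27, adjusted p = 0.0070). By the same exact test it did not pass with replicate 2 or replicate 1 alone (adjusted p = 0.24 and 0.19), with 5000 bp upstream to 1000 bp downstream (0.15), with every gene whose window holds the summit (0.13) or with all protein-coding genes as background (0.084). The translation factors eif-3.C and eif-3.E, subunits of an initiation factor, carried peaks as 2 of 23 members (Fisher's exact test, adjusted p = 0.80), also without CASSTG, and the region at eif-3.E ranked 319 in replicate 1 and 1114 in replicate 2.

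Genes reported in ADL neurons were at peaks in 2 of 13 cases (log2 odds ratio 2.69, Fisher's exact test, p = 0.066, adjusted p = 0.50). These were sre-1, with its summit 2 bp upstream of the start, and osm-9, a TRPV channel gene of sensory neurons, with its summit 228 bp upstream, and both held a CACCTG E-box. The bHLH family had 2 of 23 (Fisher's exact test, adjusted p = 0.80), hlh-4 and hlh-30, the TFEB orthologue, whose summit lay 1877 bp upstream. Neuropeptide genes had 3 of 68 (nlp-60, ins-16 and nlp-63), panneuronal genes 1 of 14 (maco-1), nuclear hormone receptors 6 of 159 (led by nhr-50, nhr-17, nhr-157 and nhr-6), and ion channel and gap junction families 1 gene, lgc-48 (0.96% of background members). Heat shock and stress genes had 3 of 92 (hsp-1, cyp-37A1 and hsp-3), collagens 2 of 78 (col-94 and col-62), and C-type lectins, lysozymes and related immune peptides 1 of 100 (fipr-13), and each of these 7 lists had an adjusted p of 1. Of the 40 genes named by the rule, 7 had a region ranked beyond 1090, a limit chosen after the ranks were seen, in 1 replicate: hlh-4, rps-1 and eif-3.E, given above, and 4 of these lists. The region at col-94 ranked 26139 in replicate 1 and 200 in replicate 2, that at col-62 ranked 4109 and 287, and that at hsp-3 ranked 3679 and 366. The region at nlp-63 ranked 386 in replicate 1 and 3487 in replicate 2.

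The other 11 lists had no gene at a peak, each with an adjusted p of 1: homeobox genes (0 of 46), ciliary genes (0 of 16), epidermal and molting genes (0 of 13), muscle genes (0 of 12), core histone genes (0 of 11), intestine genes (0 of 10), neurotransmitter synthesis and transport (0 of 9), Notch pathway genes (0 of 8), glial genes (0 of 8), germline genes (0 of 7) and pharynx genes (0 of 5).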

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

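The tests of the repeat, of GC content with 8-mers chosen on other chromosomes, of the E-box at chemoreceptor genes and of extra locus copies, as well as the search for 8-base sequences, were chosen only after the results were seen. A signal appeared outside the optimal peaks: the pooled-list regions ranked 546 to 1090 held CASSTG in 23.9% (interval 20.3% to 27.7%), against 4.60% of lower-ranked regions (Fisher's exact test, p = 6.0e-51). The share was 10.6% at ranks 1091 to 2180.

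The excess of chemoreceptor genes at peaks was weighed first, since these genes are clustered and have close paralogs. Their clustering at the 1 Mb scale is argued against as the whole cause. With target genes redrawn within 1 Mb bins, 52 chemoreceptor genes compared with a mean of 31.3 and a highest count of 49 in 10000 draws (one-sided permutation p = 0.0001, the smallest these draws can give). Location at that scale accounts for part of the excess over the 9528 genes but not all of it. Genes were redrawn singly within bins, so the draws cannot decide about clustering at shorter distances. Reads shared between paralogs are argued against too, because without the 46 peaks that hold any 36-base sequence found more than once in the genome the log2 odds ratio was 1.30 (Fisher's exact test, p = 9.8e-07). Of the 55 peaks at chemoreceptor genes, 80.0% held CASSTG against 39.2% of 268 peaks at other genes (Fisher's exact test, p = 3.2e-08), in line with the hypothesis that HLH-4 may bind these promoters through the E-box. That hypothesis was found and tested on the same peaks, and no control or mutant was analysed here. Of the 36 peaks with the other recurring sequence, described next, 35 lacked CASSTG. Most of the 36 were among the 268 peaks at other genes, which lowers the 39.2%, and the comparison without them was not tested. Peaks at paralogs were counted as independent, so the p-value may be too small where their promoters share sequence.

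A second pattern was a sequence other than the E-box. Of the 545 peaks, 36 (6.61%) held at least 3 of the 10 8-mers most over-represented in E-box-free peaks, such as CCGAGAGG and GGAGTACA, against 0.14% of lower-ranked regions, a gap that follows in part from choosing the 8-mers on these same regions and carries no independent support. Reads shared between repeat copies are argued against, as 0 of the 36 peaks (0%) had 50% or more of their 36-base sequences repeated in the genome. The 0.28% of GC-matched lower-ranked regions that held the 8-mers decides nothing about GC content, because the 8-mers were chosen as rare in those regions. With the 10 8-mers chosen instead on the other chromosomes, 27 of 274 E-box-free peaks (9.85%) and 0.36% of 274 GC-matched lower-ranked regions held at least 3 (Fisher's exact test, p = 1.2e-07), which argues against GC content as the whole cause. The sequence alone did not give a peak either, with 2.23% of 1751 such windows in the genome overlapping an optimal peak. Whether these sites need HLH-4, or are recovered with any GFP-tagged factor, stays open and was not tested, and no biological explanation was tested.

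The third pattern was the density of regions around hlh-4, where 26 pooled summits lay within 20000 bp of the start, more than at 99.1% of 19973 protein-coding genes. This is what extra copies of the locus from the transgene could give. Of 353 genes 200 kb to 1 Mb away, 98.6% had fewer, although the highest of them had 28. This argues against the wider neighbourhood alone. Genes closer than 200 kb were left out, so the comparison cannot decide about the nearer neighbourhood. Counted in steps of 10 kb on either side, the summits numbered 14, 12, 10, 8, 8 and 4 out to 60 kb, then 11, 17, 8 and 9 out to 100 kb. The steps from 60 to 80 kb, with 11 and 17 summits, were about as dense as those nearest the gene, with 14 and 12. The extent of the transgene is not given in the sources used here. Whether the hlh-4 peak reflects binding at the native gene or at the transgene stays open, and no biological explanation was tested.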

How the results depend on the processing

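Over all alternatives, 51 of 57 values that answer a comparison kept their direction and their side of the threshold, or stayed within 1.5 times for counts, and 0 reversed. Counts were compared by number alone, not by which classes, lists or chromosomes passed. With peaks that lack CASSTG the count of lists stayed at 1 and is among the 51. The list that passed there was the ribosomal protein genes and not the chemoreceptor families. Exceptions were as follows, and the cause was not tested unless given. Against GC-matched regions, 3 E-box classes were past the threshold as higher in place of 6, with fewer background regions, although all 6 ratios stayed above 1. Between the strongest and weakest 136 peaks the CASSTG difference was 16.2 percentage points and passed. Gene lists past the threshold numbered 2 in place of 1 with the upper 272 peaks, and 2 with the window of 1000 bp upstream to 200 bp downstream. Within 10000 bp of hlh-4 there was 1 peak in place of 2, by construction. As an alternative chosen after seeing the data, peaks at chemoreceptor genes were left out while the background stayed whole. This left 2 of 4 chromosomes past the threshold, I and IV being lost at −3.04 and −3.59 points against −4.15 and −4.02 with fewer peaks. V remained, at 5.59 percentage points above lower-ranked regions (exact test, adjusted p = 0.020). Also chosen afterwards, peaks without CASSTG alone turned the chemoreceptor list to a log2 odds ratio of −0.36 (exact test, adjusted p = 1), and without the peaks that hold the shared 8-mers the CASSTG difference was 48.4 percentage points against 45.1, a rise by construction since the 8-mers were picked in E-box-free peaks. Among 297 values of single classes, lists and chromosomes, 16 lost and 7 gained the threshold. The chemoreceptor list with peaks that lack CASSTG was the 1 that reversed. A change of sign was not counted where neither value passed, as for CATATG, at −0.27 points in the main setting and 0.65 with replicate 1 alone. With 1 replicate left out, the CASSTG difference ranged from 38.0 to 39.3 points and the promoter difference from 15.6 to 18.7. The background there was still drawn from the pooled list, so the left-out replicate contributed to it. Over the promoter windows the promoter difference ranged from 9.53 to 23.3. The ce10 lists gave 542 peaks, 62.4% shared top regions and 638 regions by the separate IDR fit at an IDR of 0.05. On ce11 the separate fit gave 470 regions at an IDR of 0.01. An IDR of 0.01 on the authors' peaks was not run, as the peak list gives no IDR value per peak. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on weak regions could not be assessed.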

Other observations

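The tests in this part were chosen only after the results were seen, apart from the fixed gene lists. Within the chemoreceptors, 2 of the 21 families with a background gene passed when tested one by one. The srz family had a peak at 11 of 46 members (23.9%, interval 12.6% to 38.8%; Fisher's exact test, Benjamini-Hochberg over 21 families, adjusted p = 3.9e-06), and the srh family at 17 of 133 (12.8%, interval 7.63% to 19.7%, adjusted p = 1.5e-05). By the same exact test the sri family followed with 4 of 33 (adjusted p = 0.15) and sre with 4 of 37 (adjusted p = 0.17). The str family had 4 of 92 (exact test, adjusted p = 0.91) and srw had 0 of 57 (adjusted p = 0.66), and 8 families had no gene at a peak. That srz and srh differ from the other families was not tested. Members of a family were counted as independent, so these p-values may be too small where paralogs share promoter sequence.

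With peaks that hold CASSTG alone, chemoreceptor genes made up 43 of 146 genes (log2 odds ratio 2.41, Fisher's exact test, adjusted p = 8.4e-14). With peaks that lack it, the chemoreceptor count was 10 of 171 and the ribosomal protein count was 5 (log2 odds ratio 3.38, Fisher's exact test, adjusted p = 0.0074). The ribosomal protein peaks had been seen to lack CASSTG before this split was made, so that count is not independent evidence. Peaks with no gene start in reach, 222 of the 545, held CASSTG in 55.0%, against 46.1% of the 323 others (Fisher's exact test, p = 0.045, not adjusted). The 36 peaks with the other recurring sequence were kept in this comparison. Of these 36, 35 lacked CASSTG, and most had a gene start in reach, which lowers the share among the 323. The comparison without these peaks was not tested, so the gap is not shown to hold for the remaining peaks.

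Of 32872 8-mers compared with lower-ranked regions, the highest was CAGGTGAA, in 75 peaks (13.8% against 0.34%, Fisher's exact test, adjusted p = 2.0e-72). GCAGGTGA followed in 57 peaks and ACAGGTGA in 54, and CAGCTGAA was in 40. These words hold E-boxes that are themselves more frequent at peaks, and whether the bases beside the E-box differ was not tested.

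Genes near the peaks with the other 8-mers included ced-5, wrm-1 and mib-1, named after their values were seen, beside F56G4.6, Y56A3A.7 and cux-7. The 16-base word TCCGAGAGGAGTACAC was the most common of its length among the 36 peaks, in 10 of them, and occurred in 99 places in the genome. The windows with these 8-mers that overlapped a peak lay in the promoter window in 92.3% of cases. That share was 59.3% for all optimal peak summits and 41.7% for all 1751 windows, and the difference from other peaks was not tested.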
